A study of Mus musculus with 4 samples.

How the data were processed

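Gene expression was measured by RNA sequencing in 4 libraries that the labels describe as gastric tumours of C57BL/6 mice at 20 weeks, 2 from wild-type animals (WT) and 2 from animals with an inducible deletion of Mst4 (Mst4 KO), the gene now called Stk26 in mouse and STK26 in human. The groups and replicate numbers were taken from the labels. Nothing in the labels says whether the 2 libraries of a genotype came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

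The deposited table holds 23258 genes, with an estimated count of reads per gene and library and a second, length-scaled value. HISAT2, Cufflinks and RSEM are named, per the submitters' processing notes, with no versions or roles, and the build named there is the mouse build GRCm38.p5. The estimated counts in the deposited table are not whole for most genes, and 18.8% to 23.7% of them lie within 0.005 of a whole number, zeros included. The second value is not named by the authors; it was read as FPKM because the deposited columns sum to 441772 to 452971 per library, whereas TPM would sum to the same total in each. Filters, annotation and strand setting are not given in the sources used here.

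The table does not hold mouse genes. All 23258 row identifiers begin with G9606, in which 9606 is the taxon number of human, and the symbols are human symbols. None of the gene numbers equals a mouse gene number, and 15232 symbols match a mouse symbol when letter case is ignored. A further 26 symbols had been turned into dates by spreadsheet software, and 3462 are unnamed LOC models that took 1.13% to 1.37% of the counts. The comparisons below therefore use human symbols and gene numbers as the table gives them, and WT and KO mean the libraries so labelled. No coordinates are given, because a human annotation was not used here.

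Library totals were 30505281 counts in WT replicate 1, 18804535 in WT replicate 2, 18613533 in KO replicate 1 and 18701250 in KO replicate 2. Estimated counts were rounded to whole numbers and scaled by TMM (factors 0.966, 0.984, 1.026 and 1.025). Genes were filtered with filterByExpr and tested with the quasi-likelihood test of edgeR 4.0.16 with robust dispersion, in R 4.3.3, with genotype as the only term. Benjamini-Hochberg adjusted p under 0.05 counted as a call. An SE given for edgeR is the absolute log2 fold change divided by the square root of the F statistic. DESeq2 SEs come from its own model, so they are not the same quantity. CPM values use the TMM-scaled totals. A fold against a group with 0 counts in both libraries is a lower bound against a floor of 3 counts over the group. These bounds use the library totals without the TMM factors. Such floors cover counting error only. The 95% binomial intervals (exact Clopper-Pearson) treat genes as independent draws, and cover neither the counting error of reads nor the spread between libraries. Python 3.11.15 was used for the remaining steps.

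Before the data were examined, 31 gene lists with 449 entries were fixed as mouse symbols, and 399 entries were found in the table under their human symbols. Lists with at least 3 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and adjustment over the lists, then with an estimated correlation and with fry. With an estimated correlation, camera reads its statistic on the residual degrees of freedom. These fits leave few of them, so a list can hardly pass, and not passing is weak evidence against it. The fry p-value tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. The list of sex-linked transcripts is not reported here, and members of the HLA-D family are not named.

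The named genes followed a rule fixed before the data were examined. It takes STK26 always, then the 10 largest fold changes in each direction among called genes whose KO values lie both above or both below the WT values, with at least 2 CPM in the higher genotype and without unnamed models, pseudogenes or receptor segments. It also takes up to 4 members of a described list by smallest adjusted p, with CTGF, CYR61 and ANKRD1 always. Where fewer than 5 genes pass in a direction, the 5 with the smallest p are named as not passing. After WT replicate 1 was seen to stand apart, the rule for called genes was also applied to the fit without that library and to DESeq2 1.42.0. Other genes named were chosen after their values were seen.

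The alternatives were RLE and upper-quartile scaling, no filter, a filter of 5 CPM in 2 libraries, DESeq2, limma-voom, limma-trend on log2(FPKM + 1) for genes with a mean FPKM of at least 1, each library left out in turn, the replicate number as a block, and a 2-fold limit. A fit without 1 library leaves a lone sample in its genotype, which is assumed to vary like the other genotype. The WT libraries lay further apart than the KO libraries, so p-values and SEs without a WT library do not cover the spread within WT. Chosen after seeing the data were limma-voom with sample quality weights and WT replicate 1 thinned to the depth of WT replicate 2. The weights were 0.313 and 0.308 for WT replicates 1 and 2 and 3.22 for each KO library. They marked down both WT libraries alike, and not WT replicate 1 alone. The tests were checked on simulated data drawn from the real means of 16030 genes, with 200 genes of at least 2 CPM changed. All genes and libraries were given the same dispersion, so no library could stand apart as WT replicate 1 did. The shares recovered and of false calls hold only for such data, and do not vouch for calls in the real libraries. At the dispersion of the 4 libraries (0.105), edgeR recovered 2% of the 2-fold and 65% of the 4-fold changes, with 4.29% false calls, and DESeq2 recovered 5% and 72%, with 11.5% false calls. At the dispersion estimated without WT replicate 1 (0.0115), edgeR on 1 WT and 2 KO libraries recovered 90% and 99%, with 2.58% false calls.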

Results

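The transcriptomes of 4 libraries were compared, 2 labelled as gastric tumours of WT mice and 2 as gastric tumours of Mst4 KO mice. MST4 is a serine/threonine kinase of the STRIPAK complexes, which act on the Hippo pathway. Library totals ranged from 18613533 to 30505281 counts, and WT replicate 1 was the deepest. Between 20154 and 21173 genes had a value above 0. The table lists human genes although the labels give mouse, so each gene is named by its human symbol, and WT and KO stand for the libraries so labelled.

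Transcripts of genes that have no mouse counterpart were measured in all libraries. MICA, a stress-induced ligand of natural killer cell receptors, was at 62.9, 67.6, 68.6 and 73.1 CPM in WT replicates 1 and 2 and KO replicates 1 and 2. CD58, an adhesion ligand of T cells, was at 38.3, 43.6, 45.6 and 39.9 CPM in the same order. Most markers of gastric glands were near 0, but the pit and neck marker PSCA was at 234, 119, 68.2 and 81.5 CPM and the proton pump gene ATP4A at 4.95, 7.94, 11.4 and 6.99 CPM. The mucous neck cell peptide TFF2 was at 0 in every library, and pepsinogen C (PGC) did not exceed 0.052 CPM. The mesenchymal filament gene VIM lay between 960.4 and 1270 CPM. Epithelial genes were mixed: the keratins KRT8 and KRT18 lay between 480.2 and 1759 CPM and between 566 and 988 CPM, EPCAM between 7.63 and 15.03 CPM, and the cadherin CDH1 did not exceed 0.509 CPM.

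The targeted gene, STK26 (gene number 51765), was lower in both KO libraries. It was at 54.1 and 54.8 CPM in the WT libraries (mean 54.5 ± 0.531, SD, n = 2) and at 9.06 and 7.36 CPM in the KO libraries (8.21 ± 1.20, SD, n = 2). The counts behind these values were 1594, 1015, 173 and 141. The log2 fold change was -2.73 (SE 0.26), a 6.63-fold lower level, and STK26 had the smallest p of all genes tested. It did not pass in edgeR (adjusted p = 0.834) but passed in DESeq2 (adjusted p = 8.49e-12). The log2 fold change in edgeR without WT replicate 1 was -2.74. On the deposited FPKM scale the levels were 17.2 and 17.2 in WT and 5.22 and 5.75 in KO.

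**Figure D1:**
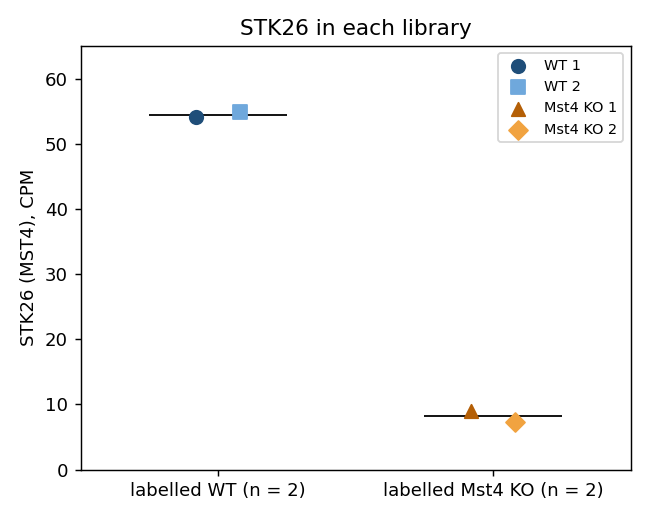
CPM of STK26 (vertical axis) in each library, by labelled genotype, with 1 point per library and a horizontal line at the mean of the 2 libraries. Both KO libraries, at 9.06 and 7.36 CPM, lie below both WT libraries, at 54.1 and 54.8 CPM.

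The comparison of KO with WT asked which genes change when MST4 is lost. Among 16030 genes tested, the edgeR quasi-likelihood test called 0 at adjusted p under 0.05. At unadjusted p under 0.05 there were 668 genes, 152 higher and 516 lower in KO, where chance alone gives about 801.5. DESeq2 called 40 genes, 6 higher and 34 lower, and limma-voom and limma-trend on FPKM called 0. Without WT replicate 1 edgeR called 1065 genes, 418 higher and 647 lower, and without WT replicate 2 it called 8702, 4271 higher and 4431 lower. The fits without a WT library take their spread from the KO libraries alone. The WT libraries lay further apart (SD of log2 differences across genes 0.844 between WT, 0.244 between KO), so those calls do not cover the spread within WT. Both KO values lay above both WT values for 2938 genes (18.3%) and below them for 3051 (19.04%), against a chance share of 16.7% in each direction.

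After STK26, the genes with the smallest p among those lower in KO were SLC7A5, C9orf84, SPOCK1 and AIRN, none of which passed in edgeR (adjusted p = 0.834 for each). All 4 passed in DESeq2 (adjusted p = 1.77e-05, 0.0042, 0.000417 and 0.00835) and in edgeR without WT replicate 1 (adjusted p at most 8.2e-10). SLC7A5, a transporter of large neutral amino acids, was at 2765 and 1822 CPM in WT and 506.4 and 596.6 CPM in KO, a log2 fold change of -2.06 (SE 0.30). SPOCK1, a matrix proteoglycan, was at 234 and 167 CPM in WT and 61.9 and 58.1 CPM in KO. C9orf84 was at 6.48 and 6.48 CPM in WT and 0.942 and 1.20 CPM in KO. AIRN, an antisense transcript of IGF2R, had 46.8 counts in each WT library and 0 in each KO library, at least 23.6-fold lower against the floor over the group. Reads of AIRN and IGF2R cannot be told apart without strand.

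Those with the smallest p among genes higher in KO were all close to the detection limit in WT, and none passed in edgeR with all 4 libraries (adjusted p = 0.834 for each). LOC105374591 had 0 counts in both WT libraries and 36.0 and 34.0 in KO, at least 30.8-fold higher on library totals without the TMM factors. SH3BGR had 0 in WT and 36.8 and 21.5 counts in KO, at least 25.7-fold higher on those totals. LOC105370750, with 31.2 and 17.9 counts in KO, was at least 21.6-fold higher on them. The antisense transcript SEC23A-AS1 had 1 count in each WT library and 31.8 and 21.3 in KO. PLBD1, a phospholipase-like protein, had 0 and 1 counts in WT and 31.1 and 37.9 in KO. DESeq2 called LOC105374591, SH3BGR and LOC105370750 higher (adjusted p = 0.00806, 0.0235 and 0.0475) but not SEC23A-AS1 (0.112) or PLBD1 (0.0544), and all 5 passed in edgeR without WT replicate 1 (adjusted p at most 0.000777).

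Several genes that DESeq2 called lower in KO in all 4 libraries had a smaller fold once WT replicate 1 was left out. NID2, a basement membrane protein, fell by 2.55 on the log2 scale (SE 0.42, DESeq2 adjusted p = 1.01e-05), with 403 and 201 CPM in WT and 48.7 and 54.7 CPM in KO. It fell by 1.95 (SE 0.15) without WT replicate 1. ITGA5, the fibronectin receptor subunit, fell by 2.57 (SE 0.61, DESeq2 adjusted p = 0.0177), but by 1.12 (SE 0.14) without WT replicate 1. The keratin gene KRT17 fell by 2.51 (SE 0.50, DESeq2 adjusted p = 0.0012), but by 1.59 (SE 0.16) without that library. ASNS, which makes asparagine, fell from 104 and 28.04 CPM in WT to 13.8 and 9.55 CPM in KO (DESeq2 adjusted p = 0.0221), and by 1.26 (SE 0.18) without WT replicate 1. CEMIP, a hyaluronan-binding protein, UNC5B, a netrin receptor, the adaptor IRS4 and carbonic anhydrase CA2 were also called lower. CEMIP was at 115 CPM in WT replicate 1 and 6.59 CPM in WT replicate 2, against 2.51 and 3.76 CPM in KO. The log2 fold changes without WT replicate 1 were -1.07 for CEMIP, -1.41 for UNC5B, -2.06 for IRS4 and -1.70 for CA2, against -4.28, -3.54, -3.51 and -2.69 in DESeq2. DESeq2 also called USP50 higher (log2 fold change 2.10, SE 0.55, adjusted p = 0.0475).

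Without WT replicate 1, further genes passed in edgeR, and the library left out went with the lower calls more than with the higher ones. WT replicate 1 lay above both KO libraries for 463 of the 647 genes called lower (71.6%, against 43.1% of genes not called). It lay below both for 216 of the 418 called higher (51.7%, against 45.4%). The calls rest on the same KO values. Both shares would therefore tend to exceed those of genes not called, even with no genotype effect in WT replicate 1. SSR1, a subunit of the translocon-associated protein complex, was at 253 and 384 CPM in WT and 111 and 94.0 CPM in KO. It fell by 1.90 (SE 0.14) without WT replicate 1. The glycerolipid acyltransferase GPAT3 fell by 1.76 (SE 0.26) and NPIPB8, a member of a multicopy family whose reads are uncertain, by 1.99 (SE 0.41). The ribosome biogenesis factor UTP14A fell by 2.69 (SE 0.23), against a value of -2.10 (SE 0.61) in all 4 libraries.

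Most of the named genes called higher in that fit had smaller fold changes, and did not pass in edgeR or DESeq2, once WT replicate 1 was included. The log2 fold change without and with that library was 2.71 (SE 0.44) and 1.64 (SE 0.62) for the endopeptidase PHEX, 3.44 (SE 0.55) and 2.44 (SE 0.61) for the zinc finger gene ZHX1, and 1.88 (SE 0.45) and 1.30 (SE 0.50) for the ceramide synthesis gene SPTLC3. It was 2.91 (SE 0.68) and 2.29 (SE 0.67) for CCDC153, and 1.75 (SE 0.43) and 0.96 (SE 0.58) for LRRC56. The FPKM values did not bear out ZHX1 (1.46 and 0.58 in WT, 1.09 and 2.28 in KO). Nor did they for CCDC153 (0.67 and 0.3 in WT, 0.46 and 0.73 in KO). For PHEX, SPTLC3 and LRRC56 both KO values lay above both WT values on that scale too. PXT1 was at 1.49 and 0.108 CPM in WT and 6.91 and 5.06 CPM in KO. WT replicate 1 was close to KO for PPAN, at 8.75 and 1.62 CPM in WT and 10.1 and 12.0 CPM in KO, and for the histone gene HIST2H2AA4, at 9.77 and 2.59 CPM in WT and 10.4 and 9.86 CPM in KO. Their log2 fold changes were 2.76 (SE 0.30) and 1.97 (SE 0.28) without WT replicate 1 and 1.07 (SE 0.78) and 0.70 (SE 0.65) with it, and those of HIST2H2BE were 1.96 (SE 0.23) and 0.96 (SE 0.54). Reads of HIST2H2AA4 and PPAN may be shared with near-identical or overlapping genes. By the rule for named genes, 137 higher and 432 lower genes qualified in this fit, after 48 and 22 unnamed models were left out.

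**Figure D2:**
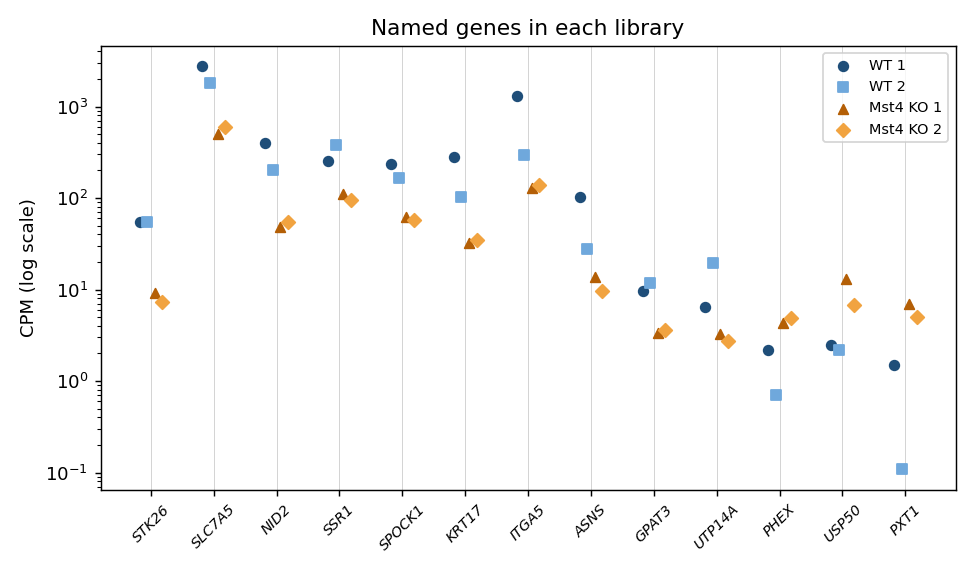
CPM on a log scale (vertical axis) of 13 named genes, with 1 point per library. STK26 and SLC7A5 are lower in both KO libraries than in both WT libraries, and ITGA5 differs more between WT replicate 1 (1301 CPM) and WT replicate 2 (292 CPM) than between WT replicate 2 and the KO libraries (129 and 139 CPM).

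The libraries did not group by genotype. Among 11960 genes with a mean of at least 5 CPM, 19.6% were over 2-fold apart between the WT libraries (95% interval 18.9% to 20.3%), and 0.334% between the KO libraries. WT replicate 2 differed over 2-fold from each KO library in 1.39% of genes, whereas WT replicate 1 differed in 20.0% and 17.7%. NDRG1, a gene induced by low oxygen, was at 3970 CPM in WT replicate 1 and at 166, 179 and 198 CPM in WT replicate 2 and the KO libraries. The Pearson correlation across genes of log2 CPM was 0.869 between the WT libraries and 0.989 between the KO libraries. The KO libraries differed by more than counting noise (chi-square per degree of freedom 9.21 across genes), so they are not copies of the same reads. Repeat preparations of 1 sample would also differ by more than counting noise, so this does not show that they came from separate animals.

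**Figure D3:**
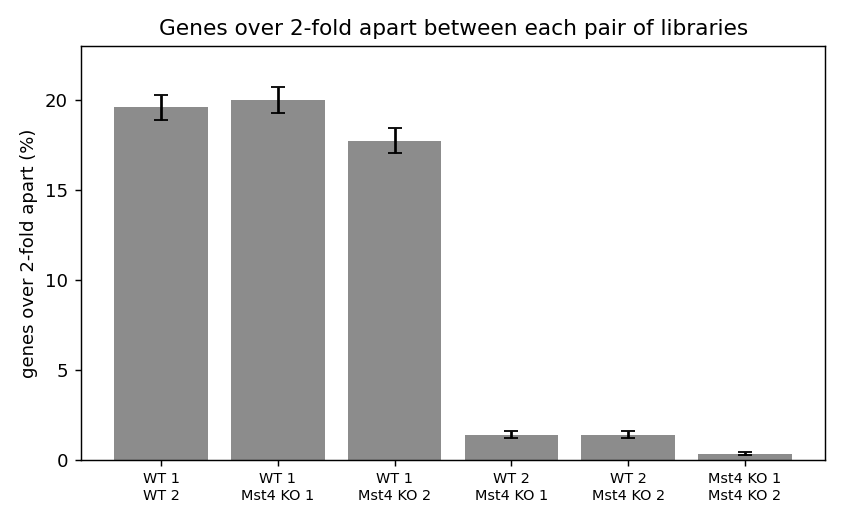
Percent of genes over 2-fold apart (vertical axis) for each pair of libraries, with 95% binomial intervals. The 3 pairs that include WT replicate 1 lie between 17.7% and 20.0%, and the other 3 pairs at 1.39% or below.

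Targets of the coactivator YAP and its TEAD partners, which the Hippo kinases restrain, were slightly lower in KO as a list. Of 22 tested members 16 were lower and 6 higher, with a mean log2 fold change of -0.48 and a median of -0.19. The list fell by camera (adjusted p = 0.0463). The adjusted p was 0.63 with an estimated correlation and 0.43 by fry. That correlation was -0.039, below the preset 0.01, so the loss came from the few residual degrees of freedom. In edgeR 0 members were called over all genes or adjusted over the list alone. FOXF2, a forkhead factor, was at 14.7 and 12.9 CPM in WT and 7.17 and 6.26 CPM in KO (log2 fold change -1.04, SE 0.30). The values were -0.74 (SE 0.25) for the growth factor TGFB2, -1.43 (SE 0.49) for the clotting initiator F3, -1.08 (SE 0.63) for CTGF, -0.06 (SE 0.25) for CYR61 and -0.52 (SE 0.57) for ANKRD1. Leaving out WT replicate 1 gave -0.94 for FOXF2, -0.606 for TGFB2, -0.655 for F3, -0.203 for CTGF, -0.24 for CYR61 and 0.083 for ANKRD1. Without WT replicate 1 the list fell with a mean of -0.21 (camera adjusted p = 0.0222, or adjusted p = 0.94 with an estimated correlation). In that fit 3 members, FOXF2, TGFB2 and MYOF, were called lower, and 5 were when adjusted over the list alone. Without WT replicate 2, KO replicate 1 or KO replicate 2 the list did not pass (adjusted p = 0.495, 0.121 and 0.182).

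Components of the Hippo pathway and of STRIPAK did not pass as a list (21 of 33 members lower, mean log2 fold change -0.14, camera adjusted p = 0.433, adjusted p = 0.64 with an estimated correlation). AMOT, with the smallest p of the list, was at 5.16 and 1.46 CPM in WT and 0.628 and 0.522 CPM in KO. Its log2 fold change was -2.52 (SE 0.75), and -1.33 without WT replicate 1, and it passed in neither edgeR nor DESeq2 with all 4 libraries. MOB1A had a log2 fold change of -0.45 (SE 0.22). YAP1 was at 262 and 249 CPM in WT and 255 and 222 CPM in KO. The paralogous kinases STK24 and STK25 had log2 fold changes of -0.32 (SE 0.28) and -0.03 (SE 0.29). The transcription factor gene TEAD1 was at 403 and 463 CPM in WT and 279 and 250.1 CPM in KO, a log2 fold change of -0.71 (SE 0.23). TEAD1 fell without WT replicate 1 by 0.80 (SE 0.14, adjusted p = 4.05e-07) and the kinase adaptor MOB1B by 0.57 (SE 0.18, adjusted p = 0.0221), the 2 members called there both over all genes and adjusted over the list alone.

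Genes induced by low oxygen were lower in KO than in WT on average, and WT replicate 1 carried the difference. All 15 members were lower, with a mean log2 fold change of -1.39 and a median of -1.48 (camera adjusted p = 4.2e-05, adjusted p = 0.63 with an estimated correlation), and 0 were called by edgeR. The carbonic anhydrase CA9 was at 707 CPM in WT replicate 1 and at 44.9, 57.2 and 70.8 CPM in WT replicate 2 and the KO libraries. Without WT replicate 1 the list had a mean of 0.07 and did not pass (adjusted p = 0.689). CA9 and ERO1A were then called higher in KO, by 0.51 (SE 0.17) and 0.53 (SE 0.16), and PGK1, a glycolytic kinase, fell by 0.61 (SE 0.13).

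A further 4 lists fell by camera in all 4 libraries, each with an adjusted p of 0.63 with an estimated correlation, and none passed without WT replicate 1. Immediate early and stress genes were lower for 12 of 14 members (mean -1.18, adjusted p = 0.000379), fibroblast and matrix genes for 12 of 13 (mean -0.98, adjusted p = 0.00125), endothelial markers for 5 of 5 (mean -0.95, adjusted p = 0.00843) and genes of epithelial-mesenchymal transition for 9 of 10 (mean -0.70, adjusted p = 0.0137). Their adjusted p without WT replicate 1 was 0.397, 0.498, 0.367 and 0.111, in the same order. The mean without that library was -0.10 for fibroblast and matrix genes, -0.48 for endothelial markers, with 4 of 5 lower, and -0.24 for transition genes, with 7 of 10 lower. The stress gene FOS was at 61.7 CPM in WT replicate 1 and at 9.94, 8.95 and 10.3 CPM in WT replicate 2 and the KO libraries. Fibronectin (FN1) was at 1640 CPM in WT replicate 1 and at 241, 196 and 204 CPM elsewhere. NR4A1, a nuclear receptor, fell without WT replicate 1 by 0.85 (SE 0.17, adjusted p = 3.9e-05), and EGR1, a zinc finger factor, rose by 1.38 (SE 0.26, adjusted p = 1.7e-05). In that fit the immediate early list had a mean of 0.49 but a median of -0.05 and a test pointing down.

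**Figure D4:**
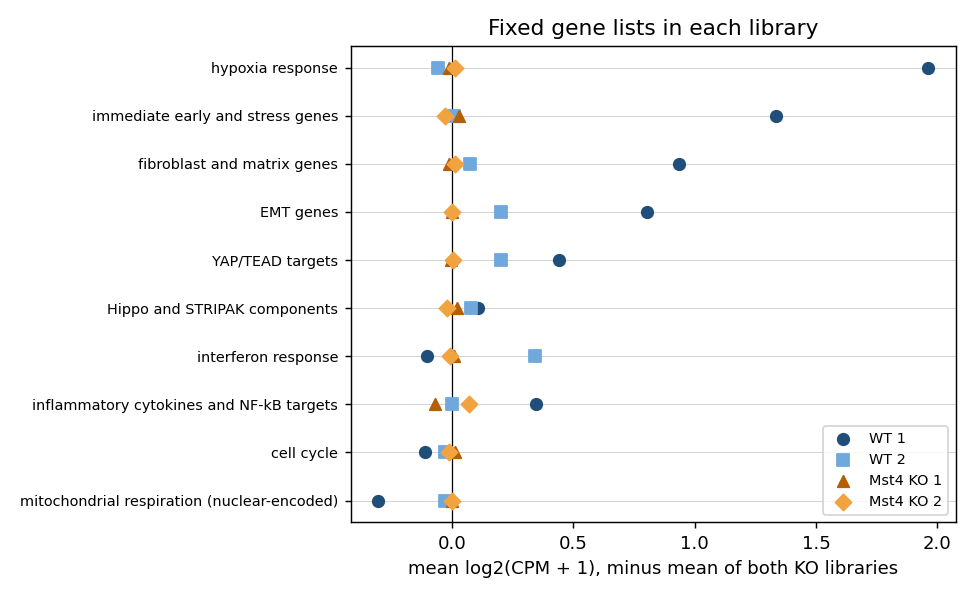
Mean log2(CPM + 1) of the members of 10 fixed gene lists (horizontal axis), as the difference from the mean of both KO libraries, with 1 point per library. WT replicate 1 lies far to the right for hypoxia, immediate early and matrix genes (hypoxia mean 8.77 against 6.75 in WT replicate 2), while WT replicate 2 lies close to the KO libraries in most lists.

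Interferon response genes did not pass in all 4 libraries (10 of 16 lower, mean -0.21, camera adjusted p = 0.549). Without WT replicate 1 the list fell (mean -0.43, camera adjusted p = 0.00608, or adjusted p = 0.94 with an estimated correlation). Without WT replicate 2 it pointed up and did not pass (11 of 16 higher, mean 0.42, camera adjusted p = 0.362). IFIT2, an antiviral protein, was at 4.44 and 35.7 CPM in WT and 10.2 and 9.97 CPM in KO, and OASL at 28.3 and 68.9 CPM in WT and 28.9 and 30.1 CPM in KO. In the fit without WT replicate 1, 7 members were called lower and 0 higher over all genes; adjusted over the list alone, 7 were lower and 1, BST2, was higher. ISG15, a ubiquitin-like modifier, was at 35.9 and 21.3 CPM in WT and 9.58 and 9.24 CPM in KO and passed in DESeq2 (adjusted p = 0.0475) but not in edgeR. Of the 7 members called, ISG15 and OAS1 were higher in WT replicate 1 than in both KO libraries, and the other 5, IFIT1, IFIT2, IFIT3, IFI44 and OASL, were lower.

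With all 4 libraries, proliferation and respiration genes did not differ by the test. Cell cycle genes were higher in KO for 24 of 34 members (mean 0.04, camera adjusted p = 0.27), and MKI67 was at 356 and 539 CPM in WT and 578 and 539 CPM in KO. Nuclear-encoded respiration genes were higher for 14 of 18 members (mean 0.15, adjusted p = 0.114). With WT replicate 2 left out, the respiration list passed (mean 0.33, camera adjusted p = 0.0223, but 0.809 with an estimated correlation) with 10 members called higher and 1 lower, and 15 cell cycle members were called higher and 9 lower. Inflammatory genes (mean -0.43, adjusted p = 0.143) and Wnt targets (mean -0.25, adjusted p = 0.649) did not pass. Among the inflammatory genes PTGS2, the inducible cyclooxygenase, was at 70.8 and 25.3 CPM in WT and 59.7 and 55.6 CPM in KO. The 13 mitochondrially encoded genes fixed as a list had no row in the table.

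Markers of most other cell types that a gastric tumour can hold were near 0, and those of fibroblasts and smooth muscle were not. The median over the measured markers lay between 14.7 and 21.4 CPM for fibroblast and matrix genes and between 3.86 and 6.00 CPM for smooth muscle, and reached 1.25 CPM for endothelial and 1.15 CPM for neutrophil markers in WT replicate 1. The median over the measured markers was at most 0.471 CPM for macrophages, 0.170 CPM for T and NK cells, 0.0848 CPM for B and plasma cells, 0.187 CPM for chief cells, 0.108 CPM for pit and neck mucous cells and 0.204 CPM for endocrine cells. It was at most 0.209 CPM for adipocyte, 0.0522 CPM for pancreatic acinar, 0.0339 CPM for liver and 0.407 CPM for skeletal muscle markers, and 0.543 CPM for MHC class II genes. These lists had fewer than 3 tested members except those of macrophages and of T and NK cells. By camera the fibroblast and matrix list and the endothelial list passed in all 4 libraries, but neither passed with an estimated correlation (adjusted p = 0.63 for each) or without WT replicate 1. The other tested marker lists did not pass in all 4 libraries. The adjusted p was 0.409 for macrophage, 0.839 for neutrophil, 0.707 for T and NK cell, 0.831 for parietal cell, 0.313 for squamous, 0.142 for intestinal, 0.549 for spasmolytic metaplasia and 0.27 for smooth muscle markers. Leaving out KO replicate 1 made the intestinal list pass, with 3 tested members (camera adjusted p = 0.00812), and leaving out 1 KO library brought skeletal muscle (KO replicate 1, adjusted p = 0.0247) and MHC class II genes (KO replicate 2, adjusted p = 0.0106) to 4 tested members, where both passed with the test pointing down. None of these 3 passed with an estimated correlation (adjusted p = 0.706, 0.706 and 0.796). In all 4 libraries without a filter, skeletal muscle (10 members) and MHC class II genes (9 members) passed by camera, both pointing down (adjusted p = 0.0221 for each). Neither passed there with an estimated correlation (adjusted p = 0.879 for each). With the filter, the mean and the median differed in sign for parietal cell markers (-0.22 and 0.16) and for T and NK cell markers (-0.02 and 0.08). MYLK, the myosin light chain kinase, was at 12.5 and 28.8 CPM in WT and 9.84 and 8.25 CPM in KO and fell by 1.67 (SE 0.19, adjusted p = 3.16e-16) without WT replicate 1.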

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

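Of the settings below, limma-voom with sample quality weights and the thinning of WT replicate 1 were chosen after the data were seen. The count of 0 called genes in edgeR stayed at 0 under RLE and upper-quartile scaling, without a filter, with the filter of 5 CPM, with a 2-fold limit, in limma-voom, on FPKM, after thinning and without either KO library. It became 40 in DESeq2, 10 with the replicate number as a block and 9 with sample quality weights, and ranged from 0 to 8702 when each library was left out, with 1065 without WT replicate 1. The replicate numbers share only a number (correlation across genes of the WT and KO differences -0.26), and the block left 1 residual degree of freedom.

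STK26 fell past the threshold in DESeq2 (-2.73), with the replicate block (-2.74, adjusted p = 0.0104) and with sample quality weights (-2.73, adjusted p = 0.00164), did not pass on the log2(FPKM + 1) scale (-1.49, adjusted p = 0.787), and ranged from -2.87 to -2.57 when each library was left out. The YAP/TEAD list kept its direction in every setting. It passed under RLE and upper-quartile scaling, in DESeq2, after thinning and without WT replicate 1. It did not pass without a filter (mean -0.47, adjusted p = 0.0736), with the filter of 5 CPM (-0.45, 0.0808), in limma-voom (-0.38, 0.0598), on FPKM (-0.22, 0.132), with the replicate block (-0.37, 0.0943), with sample quality weights (-0.38, 0.0501), with an estimated correlation (-0.48, 0.63) or by fry (-0.48, 0.43), and its mean ranged from -0.49 to -0.21 when each library was left out. The percent of genes over 2-fold apart between the WT libraries was 16.4% without a filter, 18.8% with the filter of 5 CPM and 16.3% on FPKM, against 1.501%, 0.393% and 0.532% between the KO libraries, over 22382, 11948 and 12414 genes; the FPKM row also changed the scale and the constant added.

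Signs turned when a library was left out. Over the fits that left out each library, log2 fold changes ranged from -0.24 to 0.174 for CYR61, -0.892 to 0.083 for ANKRD1, -1.89 to 0.096 for CDT1, -2.56 to 0.064 for COL5A1, -4.38 to 0.182 for NDRG1, -3.55 to 0.157 for ANKRD37 and -1.22 to 0.081 for OASL. The highest value was without WT replicate 1, except for CYR61 and OASL, where it was without WT replicate 2. List means ranged from -0.559 to 0.062 for parietal, -0.216 to 0.139 for squamous (main 0.393), -0.573 to 0.316 for macrophage, -0.727 to 0.213 for neutrophil and -1.88 to 0.516 for T and NK cell markers, from -0.428 to 0.419 for interferon genes and from -1.96 to 0.068 for hypoxia genes. The direction of the list test turned for the parietal list in limma-voom (mean -0.206), squamous markers without a filter (-0.656), metaplasia markers on FPKM (0.017), the neutrophil list in DESeq2 (-0.203) and the T and NK list without a filter (-0.145) and in DESeq2 (-0.016). The members tested also changed with the setting. Squamous markers had 3 tested members in the main fit, 4 without WT replicate 2 and 16 without a filter. T and NK cell markers had 4, 6 and 11, in the same order. Part of these list ranges and turns may therefore come from the members tested, and the cause was not tested further. Depth leaves lower bounds for genes at 0 in a group, such as AIRN and SH3BGR.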

Other observations

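The tests of depth and of length below were planned before their results were seen. The tests on genes without a mouse counterpart, on immune and endothelial markers, on the hypoxia list, on the effective length of STK26 and on ATF4 targets were chosen after the result was seen.

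WT replicate 1 differed from the other libraries in further single genes, chosen after their values were seen. ANGPTL4, a lipoprotein lipase inhibitor, was at 182 CPM there and at 5.89, 7.49 and 10.6 CPM in WT replicate 2 and the KO libraries. LOX, a collagen cross-linking enzyme, was at 287 CPM against 10.1, 8.95 and 9.18 CPM, and the imprinted transcript H19 at 861 CPM against 64.9, 48.7 and 63.1 CPM. The glycolytic enzyme GAPDH was at 14012 CPM against 6622, 5803 and 6309 CPM. In the other direction, the keratin KRT8 was at 480.2 CPM against 1759, 1171 and 1382 CPM, and the actin gene ACTB at 1405 CPM against 3741, 3181 and 3410 CPM. Exchanging labels gave 0 calls in edgeR for WT replicate 1 grouped with either KO library, with 151 and 366 genes at unadjusted p under 0.05, against 668 for the labelled genotypes; 3 splits are too few for a share under 0.05.

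Besides SLC7A5 and ASNS, some other genes of amino acid supply, chosen after their values were seen, were lower in both KO libraries. SLC3A2, the partner of SLC7A5, was at 1092 and 723.6 CPM in WT and 295 and 325 CPM in KO, and passed in DESeq2 (log2 fold change -1.55, SE 0.34, adjusted p = 0.00598). The cysteine synthesis gene CTH was at 117 and 20.3 CPM in WT and 12.1 and 10.9 CPM in KO. Others were not: the glutamine transporter SLC1A5 was at 400.1 and 236 CPM in WT and 268 and 312 CPM in KO, and MTHFD2 at 277 and 129 CPM in WT and 160.4 and 149 CPM in KO. A lower response of the transcription factor ATF4, which drives many of these genes, may account for the lower ones. Of 30 other ATF4 targets, 1 of which (ATF3) also stands among the immediate early genes, 28 were lower in KO over all libraries (mean -0.70) and 20 without WT replicate 1 (mean -0.16). The list fell by camera in limma (adjusted p = 1.87e-07 and adjusted p = 0.00741, where adjustment over 1 list changes nothing). With an estimated correlation the list did not pass in all libraries (adjusted p = 0.188) or without WT replicate 1. The estimated correlation was 0.279 and -0.03, in that order, against the preset 0.01. Without WT replicate 1 the loss therefore came from the few residual degrees of freedom and not from correlation. The list passed only at the preset correlation, and the estimated one cannot decide on the hypothesis. SHMT2, NUPR1, WARS, ALDH1L2 and EPRS fell most without WT replicate 1, by 0.60 to 1.21 on the log2 scale. In the same fit 10 of the 30 targets were higher in KO. Among them were CHAC1 (0.62), DDIT4 (0.33), DDIT3 (0.32), TRIB3 (0.14) and ATF4 itself (0.18).

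The human genes in a table labelled as mouse tumours were weighed first. Mouse reads counted against human gene models would leave genes such as MICA and CD58, which mouse lacks, near 0. Of 19 genes listed whose symbols are absent from the mouse annotation, 14 reached 1 CPM in all 4 libraries, MICA and CD58 among them. Only symbols were checked, so some of the 14 may have mouse relatives whose reads could fall on them. Tumour tissue of 1 species would bring vessels and immune cells, yet the median over 46 immune and endothelial markers was at most 0.157 CPM, with PTPRC, the leukocyte antigen, at 0.471 CPM or below. These values argue against much RNA of human leukocytes. They leave vessels open, since most of the 46 markers are leukocyte genes and the endothelial list alone had a median of 1.25 CPM in WT replicate 1 and 0.702 CPM in WT replicate 2, with 5 of 10 members at 1 CPM or more in each. They are silent on fibroblasts, whose list had a median of 14.7 to 21.4 CPM. Whether the RNA came from cultured human cells or from human cells grown in mice whose own reads were not counted, or whether the table belongs to other samples, stays open, and no biological explanation was tested.

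The distance of WT replicate 1 was weighed next. Thinning it to the depth of WT replicate 2 left 19.6% of genes over 2-fold apart, against 0.335% between the KO libraries. The values were already scaled for depth and thinning mainly adds counting noise. The share could therefore hardly have fallen, and the test cannot decide on depth. A trend with transcript length does not account for the distance, since a correction on effective length moved the share from 18.1% to 17.6%. A hypoxia-like state of that sample stays open: the median log2 difference of the hypoxia list from WT replicate 2 was 1.79, but the list had been seen to be high there, so the value cannot support it. Immediate early genes (1.85) and fibroblast and matrix genes (1.18) were also higher, and another source of the cells or a wrong label was not tested.

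The STK26 reads that remain in KO were weighed last. Cells with an intact gene mixed into the KO cells could leave such reads. If all the reads came from them, the ratio of counts to FPKM, the effective length of the transcripts, would be as in WT. That length was 0.493 of the WT value on average, 0.567 and 0.42 in the KO libraries, below the central 95% of 3766 genes of similar counts (lower bounds 0.79 and 0.779). The values argue against intact cells as the only source, since shorter transcripts or other isoforms would be needed as well. The length is a mean over transcripts, so it cannot tell what share of the reads came from intact cells. Which part of STK26 the reads cover was not analysed here.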
